A study of Caenorhabditis elegans with 20 samples.

How the data were processed

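RNA of 20 samples of mixed-stage worms in 7 groups was measured on spotted DNA microarrays, per the labels. The groups were AIN-1 IP, preimmune IP, AIN-2::GFP IP, GFP IP and 3 kinds of total lysate RNA, with 2 samples in N2 total RNA and 3 in every other group. Per the labels' protocols, RNA was taken up in Trizol, amplified once and labelled with Cy3 or Cy5 in a dye-flip scheme, and the series text speaks of independent biological replicates, so the p-values measure the spread between these samples. The deposited values are background-subtracted spot intensity on a linear scale, divided by each sample's mean. That scaling was read from the values, because 100% of them became whole numbers (within 0.001) when multiplied by 1 constant per sample, which gives back the mean signal in scanner units. Scanner, image software and background method are not given in the sources used here. No samples held identical values. Of 23232 features, 17461 have 1 gene in the probe table (16378 genes, 880 of them with more than 1 feature), 0 have several, and 5771 are not listed there. By Entrez ID 17371 probes were found in the RefSeq gene table, and 0 symbols changed.

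The linear values were quantile normalized first. Normalized values below the 10th percentile of the positive ones (0.0187 sample means) were then set to that floor, which held 32.9% of all values. After log2, gene features with a mean above the 30th percentile (12222 features, 11812 genes) were tested with limma 3.58.1 in R 4.3.3. The model fitted a mean for each of the 7 groups and the dye over all 20 samples, so that all groups share 1 estimate of the spread. Tests were two-sided, with the Benjamini-Hochberg adjusted p under 0.05 as the threshold and ± giving the standard error of a log2 difference. Counts are of features, and where a gene has several features the one with the highest mean signal stands for it. Tables and figures were made with Python 3.11.15. A background limit per sample was set at the median plus 2 MADs of 1261 chemoreceptor gene features, since the empty spots used by the study are not named in the probe table. Where no sample of a group was above it, "at least N-fold" gives, from normalized log2 values, the brighter group's mean over the dimmer group's mean of the limit or of the feature's own signal, whichever was higher, and no fold is given where this came out under 1. Features above the limit in all samples of their group numbered 7816 in the AIN-1 IP, 1096 in the preimmune IP, 7191 in the AIN-2::GFP IP, 3207 in the GFP IP, and 9614, 8141 and 7244 in total RNA of N2, AIN-2::GFP and promoter GFP worms.

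The comparisons were the AIN-1 IP and the preimmune IP against N2 total RNA, the AIN-1 IP against the preimmune IP, the AIN-2::GFP IP and the GFP IP each against total RNA of its strain, the difference between these last enrichments, and the total RNA of both transgenic strains. A feature was called AIN-1 associated when it was higher in the AIN-1 IP than in N2 total RNA and in the preimmune IP. It was called AIN-2 associated when it was higher in the AIN-2::GFP IP than in total RNA and its enrichment exceeded that of the GFP IP. The study's own definition, per its design text, asks that a gene's IP to total ratio ranks high in each replicate by a t-test against the mean rank, that its signal lies above empty spots, and that the control IP misses the same mark. It was run on the same values as an alternative, with the background limit above in place of empty spots and the threshold of 0.01.

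Camera compared each of 26 gene lists with the other genes, with the inter-gene correlation preset at 0.01 and, beside it, estimated, and adjusted over the lists of a comparison. The lists were described microRNA targets, miRISC and P-body factors, cytosolic ribosomal proteins, translation factors and tRNA synthetases, the mitochondrial respiratory chain, the proteasome, major sperm proteins, other sperm genes, collagens and cuticle, vitellogenins, muscle, neurons, neuropeptides, intestine, germline and oocyte, hypodermis and seam, core histones, heat shock and stress, nuclear hormone receptors, homeodomain factors, signalling (Wnt, Notch, Ras and TGF-beta), axon guidance and adhesion, heterochronic genes, chemoreceptors, lectins and innate immunity, and common reference genes. They were written from general knowledge of gene names. Named genes are single-gene features above the filter whose symbols consist of letters, a hyphen and a number. They were the 10 largest rises and 5 largest falls of the AIN-1 and AIN-2 comparisons, with every IP replicate on that side, and 5 of each in the control IPs and total RNA. Every measured described target and miRISC factor, up to 3 members with the smallest adjusted p of every other list, and the 10 genes with the largest mean in both associated sets completed the rule. The last part was applied to features higher over total RNA in both IPs once the overlap proved empty. The text names the genes among these that bear on each result.

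Groups, tests, lists, the naming rule and a first set of other settings were written before the data were examined. Those settings were mean scaling and cyclic loess in place of quantile normalization, no filter or a filter at the 50th percentile, 50 scanner units added before log2 in place of the floor, no dye term, a fit of only the groups compared, a trended and robust variance, the replicate number as a block, same-numbered samples of opposite dye as a random block (they may share an array), the study's t-test, and leaving out each sample in turn. The settings added after the data were seen are named in the closing section.

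Replicate numbers come from the sample titles. Same-numbered samples deviated together from their group means in the AIN-1 and preimmune IPs (correlations 0.199 to 0.384, against -0.212 to -0.0418 for other numbers). They did so too in the AIN-2::GFP and GFP IPs (0.257 to 0.52, against -0.301 to -0.0565) and in the total RNA of both transgenic strains (0.591 to 0.769, against -0.45 to -0.264). The numbers therefore pair these samples, by the data and not by a statement of the labels.

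The procedure was tested on simulated data, in which 67, 67 and 66 of 12222 features were changed by 1, 2 and 3 on the log2 scale. Of those changed by 3, limma called 19.7% for the AIN-1 IP and 24.2% for the preimmune IP against N2 total RNA, 37.9% for the AIN-1 IP against the preimmune IP, 13.6% for the AIN-2::GFP IP, 34.8% for the GFP IP, 1.52% for the difference of enrichments and 27.3% for total RNA. Of those changed by 2, in the same order, it called 4.48%, 5.97%, 17.9%, 5.97%, 5.97%, 2.99% and 7.46%. Of those changed by 1 it called 4.48% for the AIN-1 IP against the preimmune IP and 0% in the other comparisons. Unchanged features called numbered 0, 2, 39, 0, 5, 0 and 0. In a camera test a list moved by 1 on the log2 scale in the AIN-2::GFP IP was called, and 0 of 25 other lists were. The median standard error of a log2 difference was 0.84, 0.762, 0.748 and 1.06 for the AIN-1 IP against N2 total RNA and against the preimmune IP, the AIN-2::GFP IP against total RNA and the difference of enrichments. Features without a gene in the probe table were left out of the comparisons because no list or name applies to them, and are described in the closing section.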

Results

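RNA from 20 samples of mixed-stage Caenorhabditis elegans was profiled on spotted microarrays to find mRNAs bound by AIN-1 and AIN-2, the worm's GW182-family partners of the microRNA Argonautes. RNA came from immunoprecipitates (IPs) of wild-type N2 worms with AIN-1 antibody (n = 3) or preimmune serum (n = 3), and from GFP immunoprecipitates of worms that carried AIN-2::GFP (n = 3) or GFP alone under the ain-2 promoter (n = 3). Total lysate RNA came from N2 (n = 2), the AIN-2::GFP strain (n = 3) and the ain-2 promoter GFP strain (n = 3). The array held 23232 features, of which 17461 had 1 gene in the probe table, and 12222 of these (11812 genes) passed the low-signal filter. The number of arrays limits the precision of every comparison.

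The control immunoprecipitates were far dimmer than the others, except for GFP IP replicate 1. Mean signal was 781 ± 141 scanner units (SD, n = 3) in the AIN-1 IP and 32 ± 20.2 (SD, n = 3) in the preimmune IP. It was 557 ± 206 (SD, n = 3) in the AIN-2::GFP IP and 143 ± 198 (SD, n = 3) in the GFP IP, where replicate 1 reached 370 and replicates 2 and 3 reached 46 and 12. The N2 total RNA samples had means of 472 and 800, and the transgenic total RNA groups had means of 533 ± 47.5 and 437 ± 228 (SD, n = 3 each). In the preimmune samples 10.2%, 28.2% and 27.1% of the gene features lay above the background limit. In GFP IP replicates 1, 2 and 3 this was 54.8%, 27.3% and 25%, against 45.6% to 62.7% in the other samples. Rank correlations across features between replicates were 0.915 to 0.916 in the AIN-1 IP and 0.855 to 0.87 in the AIN-2::GFP IP, but 0.263 to 0.691 in the preimmune IP and 0.605 to 0.739 in the GFP IP.

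**Figure D1:**
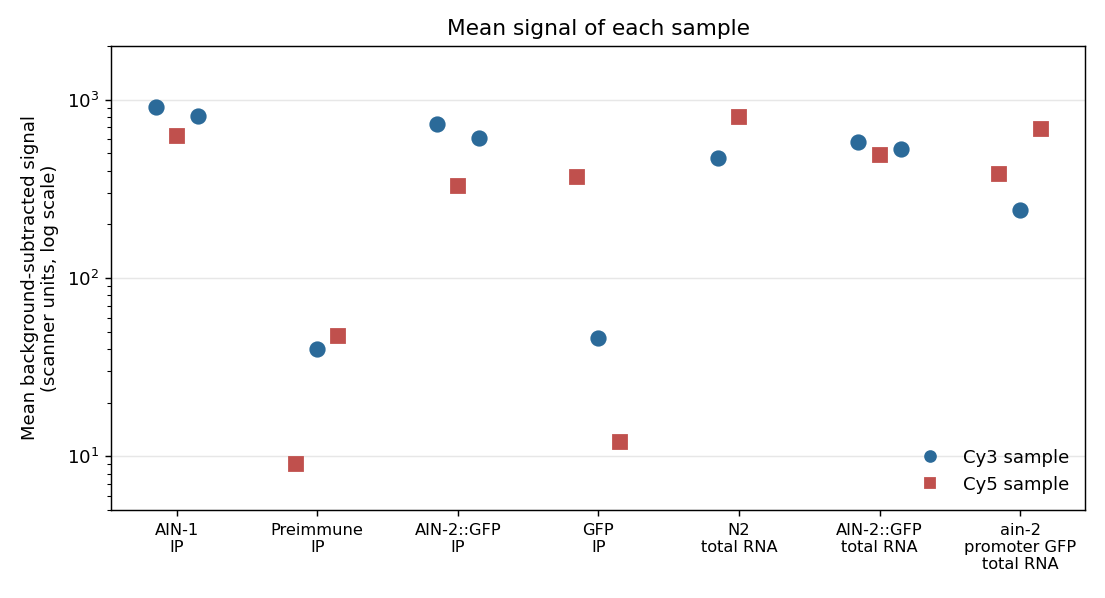
Mean background-subtracted signal of each of the 20 samples in scanner units on a log axis, by group, with Cy3 samples as circles and Cy5 samples as squares. The preimmune samples lie at 9, 40 and 47 and GFP IP replicates 2 and 3 at 46 and 12, below every sample of the other groups (241 or more).

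The AIN-1 IP was compared with N2 total RNA to ask which mRNAs were enriched over their level in the same strain. Among the largest rises that held without any single sample were twk-28, a potassium channel gene, at least 20.4-fold (limma, adjusted p = 7.87e-04, n = 3 and 2), and bus-28, at least 23.4-fold (adjusted p = 0.00248; 0.0865 with the array set described below as a covariate). The gene iglr-1 rose by 4.71 ± 0.56 log2 (SE, adjusted p = 2.56e-04), and sup-18 by 4.10 ± 0.65 (adjusted p = 0.0012). Among genes of the naming rule cuticle collagens fell most: col-98 changed by -7.51 ± 0.82 (adjusted p = 1.32e-04) and col-117 by -7.41 ± 0.76 (adjusted p = 8.73e-05). The ribosomal protein mRNA rpl-37A fell by 5.28 on the log2 scale (SE 0.47, adjusted p = 5.41e-05). The hypodermal transcription factor hbl-1, a described microRNA target of the heterochronic pathway, rose by 2.48 ± 0.51 (adjusted p = 0.00644). That call was lost without N2 total RNA replicate 1 (adjusted p = 0.0966) or replicate 2 (adjusted p = 0.062) and with the array set as a covariate (adjusted p = 0.147).

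The Notch receptor gene lin-12 rose by 3.13 ± 0.53 in the AIN-1 IP over N2 total RNA (adjusted p = 0.00197), although it missed the threshold under mean scaling (adjusted p = 0.0531). The Wnt effector pop-1 was at least 12.1-fold higher (adjusted p = 0.0012), but against the 6 transgenic total RNA samples its difference was 1.22 (adjusted p = 0.134). The Argonaute gene alg-2 rose by 1.58 ± 0.40 (adjusted p = 0.0184) and ain-1 itself by 2.08 ± 0.56 (adjusted p = 0.0256). The ain-1 call was lost without any 1 of the 5 samples, with adjusted p of up to 0.195 without N2 total RNA replicate 2. The alg-2 call was lost without AIN-1 IP replicate 2 or 3 and without N2 total RNA replicate 1 or 2, with adjusted p of up to 0.233. It was also lost under either other scaling. Among genes of the naming rule the 2 largest rises were cdc-42, at least 317-fold (adjusted p = 0.0226), and the protease gene asp-6, at least 54.5-fold (adjusted p = 0.0462). Both spots were above the background limit in every AIN-1 IP and preimmune sample and in replicate 1 of the AIN-2::GFP and GFP IPs. They were below it in all total RNA samples and AIN-2::GFP IP replicates 2 and 3. With that array set, chosen after the data were seen and found in part from these spots, as a covariate, cdc-42 differed by 0.35 (adjusted p = 0.749) and asp-6 by 0.18 (adjusted p = 0.966). Their calls were also lost without each of the 5 samples in turn, with adjusted p of up to 0.166 and 0.26 respectively.

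In this comparison 59 of 66 cytosolic ribosomal protein genes fell (61 adjusted over the list alone), with a median of -2.94 (camera, adjusted p = 1.26e-45; adjusted p = 0.0581 with an estimated correlation). Of 138 collagen and cuticle genes 52 fell and 1 rose (65 and 2 adjusted over the list alone), with a median of -1.83 (adjusted p = 4.28e-19; 0.0516 with an estimated correlation). Of 37 respiratory chain genes 14 fell (15 adjusted over the list alone), and the median was -1.77 (adjusted p = 1e-08; 0.206 with an estimated correlation). Of 19 muscle genes 7 fell (10 fell and 1 rose adjusted over the list alone), with a median of -1.83 (adjusted p = 0.00132; 0.236 with an estimated correlation). Of 53 translation factor genes 7 fell, including the elongation factor eef-2 at -3.42 ± 0.55, with a median of -0.82 (adjusted p = 2.71e-04; 0.313 with an estimated correlation). Lower medians were also found for 31 proteasome genes (-0.87, 3 fell, adjusted p = 0.0174; 0.456 with an estimated correlation) and 22 intestinal genes (-1.07, 3 fell and 1 rose, adjusted p = 0.0174; 0.33 with an estimated correlation). The median was -0.52 for 76 neuropeptide genes (8 fell and 4 rose, adjusted p = 0.0174; 0.281 with an estimated correlation) and lower than 0 as well for 33 germline genes (-0.36, 5 fell, adjusted p = 0.0479; 0.527 with an estimated correlation). The yolk protein genes had a median of -1.69 over 6 members, of which 2 fell, vit-6 (-2.91 ± 0.51) and vit-4 (-1.86 ± 0.53, with another probe of the opposite sign), at adjusted p = 0.00344 (0.0516 with an estimated correlation).

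The chemoreceptor genes were the list whose higher level held with an estimated correlation: 46 of 472 rose and 3 fell (45 and 2 adjusted over the list alone), with a median of 1.10 (adjusted p = 2.79e-07; 0.015 with an estimated correlation). Against the 6 transgenic total RNA samples its median was 0.54 (adjusted p = 0.0014; 0.1 with an estimated correlation). The list was about as high in the preimmune IP (0.99), and the background limit was set from chemoreceptor features. Of 144 nuclear hormone receptor genes 16 rose and 2 fell, with a median of 0.71 (adjusted p = 0.0064; 0.0581 with an estimated correlation). All 10 measured described microRNA targets lay above 0, with a median of 0.94 (adjusted p = 0.0109; 0.226 with an estimated correlation), although hbl-1 was the 1 member past the test. The 6 heterochronic genes had a median of 1.16 (1 rose, adjusted p = 0.0479; 0.189 with an estimated correlation). The medians were 0.90 for 24 axon guidance and adhesion genes (1 rose and 1 fell, adjusted p = 0.0479; 0.405 with an estimated correlation) and 0.59 for 40 sperm genes other than major sperm protein genes (4 rose and 1 fell, adjusted p = 0.0479; 0.234 with an estimated correlation). Of the 26 lists, 10 missed the threshold. Their medians were 0.34 for miRISC and P-body factors (2 of 14 rose), 0.10 for major sperm protein genes, -0.41 for neuronal, 0.52 for hypodermal, -0.20 for histone, -0.37 for heat shock, 0.56 for homeodomain, 0.42 for signalling, 0.02 for lectin and immunity and -0.34 for common reference genes.

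In all, 746 features were higher and 691 lower in the AIN-1 IP than in N2 total RNA, with an all-feature median of 0.11. Under mean scaling it was -1.02, with 229 features higher and 1810 lower. Relative to all features, the vitellogenin median then turned from -1.81 to 0.65 (adjusted p = 0.723) and the germline median from -0.47 to 0.08 (adjusted p = 0.467). The medians of the histone, reference and major sperm protein lists turned to 0.12, 0.69 and 0.32. The nuclear hormone receptor and other sperm medians then lay below 0 (-0.42 and -0.34) but above the all-feature median by 0.57 and 0.65. That scaling also ended the calls of the proteasome (adjusted p = 0.495), other sperm (0.141), muscle (0.119), neuropeptide (0.152), intestinal (0.397) and heterochronic lists (0.119). Cyclic loess turned the miRISC median to -0.13 relative to all features and ended the heterochronic (adjusted p = 0.121) and axon guidance calls (0.0691). Without the low-signal filter the nuclear hormone receptor (adjusted p = 0.0887) and other sperm calls (0.107) were lost, and the chemoreceptor median relative to all features fell from 0.99 to 0.07 (0.00685). With the array set as a covariate the described target (0.061), heterochronic (0.0738), axon guidance (0.0964), germline (0.122) and other sperm (0.129) calls were lost. Against the 6 transgenic total RNA samples the muscle (median -0.38, adjusted p = 0.376) and intestinal calls (-0.50, 0.298) were lost, and the neuropeptide (0.20, 0.298) and other sperm medians (-0.41, 0.0836) changed sign. Major sperm protein genes (-3.22, 4.8e-08) and hypodermal genes (0.94, 0.0197) passed there, the miRISC and lectin medians turned to -0.56 and -0.21 (0.335 and 0.376), and the germline and axon guidance medians were -1.22 and 0.59 (2.27e-05 and 0.0358). With the N2 samples as sharing 1 array, in a random block, 981 features passed and no list call was lost (camera on t statistics). The count fell from 1437 to 778, 475 and 882 without AIN-1 IP replicates 1, 2 and 3 and to 301 and 278 without N2 total RNA replicates 1 and 2. Of the called values of named genes, 31 of the 83 stayed past the test in all 5 of these fits. Without N2 total RNA replicate 1 the proteasome (adjusted p = 0.0545) and neuropeptide (0.0673) calls were lost, and the axon guidance, heterochronic, germline and other sperm calls were each lost in 2 or more of the 5 fits (up to 0.149).

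The preimmune IP of the same worms was compared with N2 total RNA as the background of that enrichment. Collagen mRNAs were again among the largest falls, with col-180 at -8.82 ± 1.29 (limma, adjusted p = 7.9e-04, n = 3 and 2) and col-98 at least 16.6-fold lower (adjusted p = 6.25e-05). The ribosomal protein mRNAs rps-20 and rpl-37A fell by 2.84 and 3.05 on the log2 scale (SE 0.41 and 0.47; adjusted p = 6.49e-04 and 0.00119). Chemoreceptor genes included srab-18, at least 8.45-fold higher (adjusted p = 4.34e-04), and srg-28, at least 8.65-fold higher (adjusted p = 6.42e-04). The gene cdc-42 was at least 236-fold higher (adjusted p = 0.0278), a call lost without N2 total RNA replicate 1 or 2 (adjusted p = 0.138 and 0.225). With the array set as a covariate it was lost, at -0.07. The described target hbl-1 differed by 0.58 ± 0.51 (adjusted p = 0.465) and ain-1 by 0.40 (adjusted p = 0.658).

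Of 138 collagen and cuticle genes 45 fell and 1 rose in the preimmune IP (63 and 2 adjusted over the list alone), with a median of -1.52 (camera, adjusted p = 2.7e-08; 0.289 with an estimated correlation). Of 66 ribosomal protein genes 18 fell (30 adjusted over the list alone), with a median of -1.32 (adjusted p = 1.63e-08; 0.527 with an estimated correlation). Of 472 chemoreceptor genes 63 rose and 8 fell (66 and 9 adjusted over the list alone), with a median of 0.99 (adjusted p = 5.69e-12; 0.00118 with an estimated correlation). Of 6 vitellogenin genes 5 fell, with a median of -2.91 (adjusted p = 0.00176; 0.0414 with an estimated correlation). That call was lost under mean scaling (0.237) and cyclic loess (0.0924). Lower medians were found for muscle (-2.27, 10 of 19 fell, adjusted p = 0.00243; 0.512 with an estimated correlation), the respiratory chain (-1.42, 8 fell, adjusted p = 0.00243; 0.527) and histones (-1.53, 5 fell, adjusted p = 0.00148; 0.527). So were those of neuropeptides (-1.19, 14 fell, adjusted p = 0.00694; 0.462) and translation factors (-1.43, adjusted p = 0.0116; 0.585), the last value of each being the adjusted p with an estimated correlation. Higher medians were found for nuclear hormone receptors (0.48, 12 rose and 8 fell, adjusted p = 0.00694; 0.0905 with an estimated correlation) and other sperm genes (0.48, adjusted p = 0.0193; 0.289 with an estimated correlation). Under mean scaling both lay at -0.43, still 0.85 above the median of all features. The described microRNA targets had a median of 0.29 with 6 of 10 above 0 (adjusted p = 0.501). It turned to -0.73 under mean scaling, 0.55 above the median of all features.

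In total 476 features were higher and 1121 lower, with an all-feature median of -0.41. The split was 276 to 2369 (median -1.27) under mean scaling and 632 to 723 (median -0.06) under cyclic loess, which also ended the translation factor (adjusted p = 0.0567), nuclear hormone receptor (0.101) and other sperm calls (0.0597). The array set as a covariate ended the translation factor (0.0563) and other sperm calls (0.0949). Without the low-signal filter the chemoreceptor median relative to all features was 0.88, against 1.41. The count of 1597 became 2618 and 2559 without preimmune replicates 2 and 3 and 435 and 161 without N2 total RNA replicates 1 and 2. Without preimmune replicate 1, where it was 1716, the translation factor (0.176), nuclear hormone receptor (0.176) and other sperm (0.342) calls were lost. The preimmune and AIN-1 comparisons share the N2 total RNA samples, so agreement between them is not independent.

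The AIN-1 IP was next compared directly with the preimmune IP, the test of enrichment over nonspecific recovery. The nicotinic acetylcholine receptor gene lev-1 was at least 4.06-fold higher (limma, adjusted p = 2.3e-04, n = 3 and 3), the neuropeptide gene nlp-101 at least 3.49-fold (adjusted p = 8.19e-04) and sup-18 at least 3.66-fold (adjusted p = 2.3e-04). The neuropeptide receptor gene npr-29 rose by 5.02 ± 0.95 (adjusted p = 0.00399). Of the described microRNA targets, hbl-1 rose by 1.91 ± 0.46 (adjusted p = 0.0161) and the cell death gene egl-1 by 3.86 ± 0.78 (adjusted p = 0.00564), and ain-1 rose by 1.68 ± 0.51 (adjusted p = 0.0436). Among the falls, oac-22 was at least 12.3-fold lower (adjusted p = 0.00259) and rad-50 fell by 4.81 on the log2 scale (SE 0.97, adjusted p = 0.00564). The hbl-1 call was lost without AIN-1 IP replicate 1 (adjusted p = 0.056) or 2 (0.11), and the ain-1 call without any AIN-1 IP replicate or preimmune replicate 1 (up to 0.181). The calls of egl-1, lev-1, nlp-101, sup-18 and npr-29 held in all 6 leave-one-out fits. For lin-12 (adjusted p = 1.33e-04), the TGF-beta receptor gene daf-1 (0.00113), the netrin gene unc-6 (0.00313) and the neuronal gene unc-119 (4.33e-04), all higher in the AIN-1 IP, no preimmune sample was above background and the limit there left no fold to give.

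Of 24 histone genes 6 rose against the preimmune IP (9 adjusted over the list alone), with a median of 1.49 (camera, adjusted p = 0.00424; 0.67 with an estimated correlation). Among them were the linker histone gene his-24 (3.63 ± 0.62, adjusted p = 0.00213) and his-62 (3.08 ± 0.65, adjusted p = 0.00745). Of 24 axon guidance and adhesion genes 6 rose (12 adjusted over the list alone), with a median of 1.23 (adjusted p = 0.0011; 0.427 with an estimated correlation). Of 66 ribosomal protein genes 35 fell (50 adjusted over the list alone), with a median of -1.63 (adjusted p = 3.64e-31; 0.385 with an estimated correlation). They included rpl-37.2 (-2.21 ± 0.38), rps-3A (-2.09 ± 0.36) and rpl-10L (-2.15 ± 0.39). Their own calls were lost under mean scaling. The respiratory chain had a median of -0.15 (1 fell, adjusted p = 0.00919; 0.67 with an estimated correlation) and the germline list -0.17 (4 fell and 1 rose, adjusted p = 0.0221; 0.67 with an estimated correlation). Under mean scaling both calls were lost (adjusted p = 0.592 and 0.511), with medians relative to all features of -0.22 and -0.18, against -0.58 and -0.60. Of the collagen and cuticle genes 4 rose and 2 fell, with a median of -0.21 (adjusted p = 0.00424; 0.67 with an estimated correlation). Without the low-signal filter the respiratory chain (adjusted p = 0.0641), germline (0.201) and collagen calls (0.0982) were lost. The respiratory chain call was lost without preimmune replicates 2 and 3 (adjusted p = 0.164 and 0.289) and the collagen call without preimmune replicate 3 (0.147). The germline call was lost without AIN-1 IP replicate 1 (0.0528) and preimmune replicates 2 and 3 (0.356 and 0.218). Relative to all features these medians stayed below 0 in the leave-one-out fits. Of the 10 described microRNA targets 9 lay above 0, 2 rose (3 adjusted over the list alone) and the median was 1.06, short of the threshold (adjusted p = 0.0946; 0.00951 under mean scaling). The chemoreceptor list, which was high in either IP over N2 total RNA, had a median of 0.05, or -0.38 relative to all features (35 rose, 14 fell, adjusted p = 0.092). It passed as lower under mean scaling (-0.73 relative to all features, adjusted p = 0.0153) and without the filter (5.16e-04).

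Against the preimmune IP 1154 features were higher and 289 lower (80% higher), with an all-feature median of 0.42, and 82 of these calls had both groups below background. The split was 1291 to 600 (68.3% higher, median 0.19) under mean scaling, 930 to 739 (55.7% higher, median 0.04) under cyclic loess and 1265 to 438 with array quality weights. The weights were added after the data were seen, because simulated data here gave 39 false calls (unchanged features) without them and 1 with them. Changed features called without them numbered 3, 12 and 25 by size, so false calls far exceeded the 0.05 threshold. Same-numbered AIN-1 and preimmune samples deviated together, and with the replicate as a block 0 features passed the limma test (1000 at an unadjusted p under 0.05), while the 6 list calls held. With only the 6 samples compared in the fit, 0 features passed (1476 at an unadjusted p under 0.05). The count of 1443 became 674, 519 and 785 without AIN-1 IP replicates 1, 2 and 3 and 2497 and 2181 without preimmune replicates 2 and 3.

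By the combined criterion 316 features were AIN-1 associated (higher than in N2 total RNA and, in a test prone to false calls, the preimmune IP). They included lin-12, his-24, iglr-1, sup-18, hbl-1 and ain-1. The number was 148 under mean scaling and 0 with the replicate block or with only the groups compared. It was 134, 75 and 164 without AIN-1 IP replicates 1, 2 and 3 and 65 and 74 without N2 total RNA replicates 1 and 2.

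The AIN-2::GFP IP was compared with total RNA of the AIN-2::GFP strain to ask the same question of AIN-2. The gene sup-18 rose by 5.41 ± 0.58 (limma, adjusted p = 3.63e-04, n = 3 and 3). The BMP pathway gene smoc-1 was at least 17.6-fold higher (adjusted p = 3.63e-04), npr-29 at least 15.5-fold (adjusted p = 0.00737), pals-40 at least 13.6-fold (adjusted p = 0.00128) and the tyramine-gated channel gene lgc-55 at least 12.7-fold (adjusted p = 0.00608). The described target hbl-1 rose by 2.79 ± 0.46 (adjusted p = 0.00245), and these calls held without any 1 of the 6 samples. Among the largest falls were rpl-27 at -3.89 ± 0.44 (adjusted p = 3.63e-04), rpl-35 at -3.65 ± 0.52 (adjusted p = 9.97e-04) and fau-1, which encodes a ubiquitin-like ribosomal protein fusion outside the list's naming rule, at -3.63 ± 0.50 (adjusted p = 6.89e-04). The intestinal protease gene asp-1 fell by 2.96 on the log2 scale (SE 0.44, adjusted p = 0.00127). The yolk protein gene vit-2 rose by 2.47 ± 0.53 (adjusted p = 0.0126). Its call was lost under both other scalings and without AIN-2::GFP IP replicate 1 (adjusted p = 0.0561) or AIN-2::GFP total RNA replicates 1 (0.07) and 3 (0.0647). The heterochronic gene lin-66 was at least 1.55-fold higher (adjusted p = 0.0179). That call was lost without AIN-2::GFP IP replicate 3 (0.0786) or AIN-2::GFP total RNA replicates 1 (0.104) and 2 (0.0661). The gene ain-1 differed by 1.05 (adjusted p = 0.257).

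Of 66 ribosomal protein genes 60 fell in the AIN-2::GFP IP (63 adjusted over the list alone), with a median of -3.06 (camera, adjusted p = 3.59e-63; 0.0356 with an estimated correlation). The 6 heterochronic genes had a median of 1.76, 2 of them past the test (4 adjusted over the list alone), at adjusted p = 2.26e-04 (0.0188 with an estimated correlation). The 144 nuclear hormone receptor genes had a median of 0.55, with 8 rises and 1 fall (11 rises adjusted over the list alone), at adjusted p = 4.5e-05 (0.0188 with an estimated correlation). All 10 described microRNA targets lay above 0, 1 of them past the test (5 adjusted over the list alone), with a median of 1.15 (adjusted p = 1.28e-04; 0.0959 with an estimated correlation). The hypodermal list had a median of 0.54 (1 rose, 3 adjusted over the list alone, adjusted p = 0.00803; 0.0959 with an estimated correlation), and axon guidance 0.50 (1 rose, adjusted p = 0.00803; 0.329 with an estimated correlation). The median was 0.38 for signalling (3 rose, adjusted p = 0.0257; 0.343 with an estimated correlation) and 0.37 for chemoreceptors (5 rose, 1 fell, adjusted p = 0.013; 0.15 with an estimated correlation). Lower medians were found for the respiratory chain (-1.56, 8 fell, 14 adjusted over the list alone, adjusted p = 2.37e-09; 0.159 with an estimated correlation), collagens (-1.17, 15 fell and 1 rose, 18 and 1 adjusted over the list alone, adjusted p = 9.07e-08; 0.176) and translation factors (-0.96, 5 fell, 8 adjusted over the list alone, adjusted p = 4.5e-05; 0.322). The same held for major sperm protein genes (-1.62, 1 fell, 4 adjusted over the list alone, adjusted p = 4.75e-04; 0.322), the proteasome (-1.31, 1 fell, adjusted p = 6.26e-04; 0.342), germline genes (-0.75, 2 fell and 1 rose, adjusted p = 0.00125; 0.342) and intestinal genes (-1.13, 2 fell, adjusted p = 0.0164; 0.342), the last value being the adjusted p with an estimated correlation. The vitellogenin list did not stand apart (median -0.04, 1 rose, adjusted p = 0.59).

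Together 341 features were higher and 332 lower in the AIN-2::GFP IP than in total RNA, against 149 and 429 under mean scaling. That scaling moved the all-feature median from -0.00 to -0.42, ended the intestinal call (adjusted p = 0.0637) and turned the chemoreceptor median to -0.02, though relative to all features it stayed at 0.39. The count of 673 became 326, 222 and 388 without AIN-2::GFP IP replicates 1, 2 and 3 and 228, 280 and 256 without AIN-2::GFP total RNA replicates 1, 2 and 3. Of the 63 called values of named genes, 26 stayed past the test in all 6 fits. The intestinal call was lost without AIN-2::GFP IP replicate 3 (0.0674), and the signalling call without AIN-2::GFP IP replicate 2 (0.0646). The chemoreceptor call was lost without AIN-2::GFP IP replicate 3 (0.0815) or AIN-2::GFP total RNA replicate 2 (0.0818). It was also lost without the low-signal filter (0.122), where its median equalled that of all features and the nuclear hormone receptor median relative to all features fell from 0.55 to 0.10 (0.00516).

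**Figure D2:**
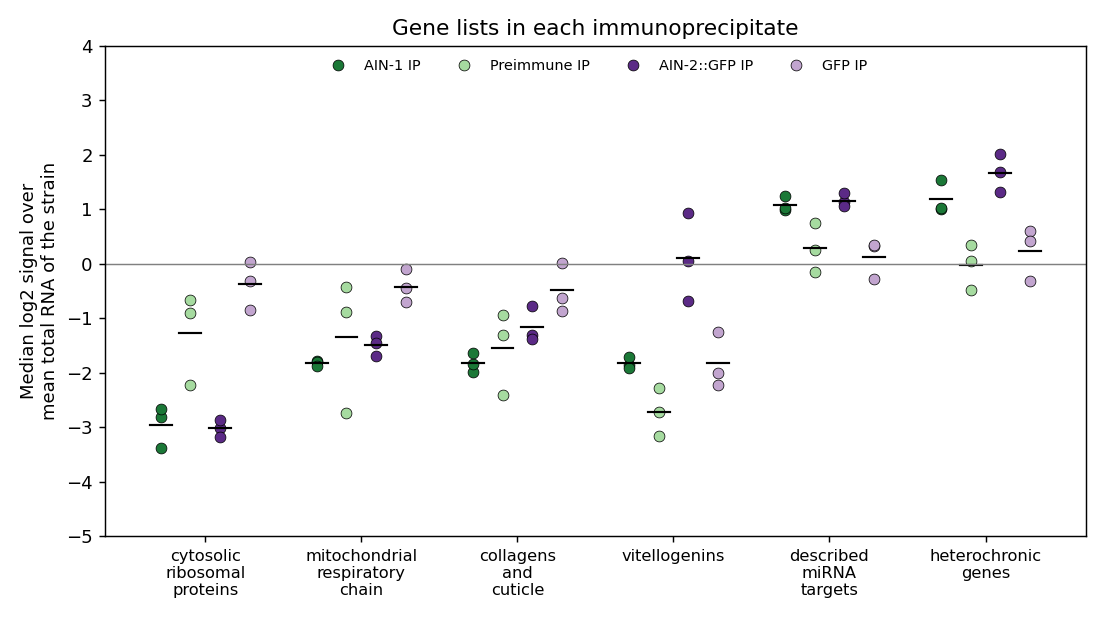
Median log2 signal over the mean total RNA of the strain for 6 gene lists, with 1 point per IP sample and a black bar at the mean of each group of 3. Ribosomal protein genes lie between -3.38 and -2.66 in the AIN-1 IP and between -3.18 and -2.87 in the AIN-2::GFP IP, against -0.85 to 0.03 in the GFP IP, while the vitellogenin level relative to all features in the AIN-1 IP turns positive under mean scaling.

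The GFP IP of the ain-2 promoter GFP strain, the control for AIN-2::GFP, differed from its total RNA at 3 features. The genes sra-4 and eif-3.J were lower (limma, adjusted p = 0.0316 each, n = 3 and 3) with no GFP IP sample above background, and F46C3.2, which lay outside the naming rule and was named after its value was seen, was at least 2.43-fold higher (adjusted p = 0.0316). The vitellogenin list had a median of -1.92 with 0 of 6 members above 0 and 5 lower adjusted over the list alone (camera, adjusted p = 1.59e-04; 0.0149 with an estimated correlation; 0.406 under cyclic loess). Collagens had a median of -0.48 (13 lower and 1 higher adjusted over the list alone, adjusted p = 0.0276; 0.948 with an estimated correlation), nuclear hormone receptors 0.15 (adjusted p = 0.00526; 0.0537 with an estimated correlation) and chemoreceptors 0.18 (adjusted p = 0.00115; 0.0537 with an estimated correlation). These 3 calls were lost under cyclic loess (0.0941 each). Ribosomal protein genes had a median of -0.41 (adjusted p = 0.0549), described microRNA targets 0.15 (adjusted p = 0.38) and heterochronic genes 0.23 (adjusted p = 0.38). At an unadjusted p under 0.05, 1338 features differed. The all-feature median was -0.22 (-0.18 under mean scaling and -0.02 under cyclic loess). Without GFP IP replicate 1, 573 features passed, and without any 1 of the other 5 samples 0 passed in limma (905 to 1236 at an unadjusted p under 0.05). The collagen call was lost without GFP IP replicates 2 and 3 (adjusted p = 0.0936 and 0.14) and promoter GFP total RNA replicate 1 (0.183). The receptor calls were lost without GFP IP replicate 2 (0.0936 each).

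The difference between both enrichments, AIN-2::GFP IP over its total RNA minus GFP IP over its own, asked which mRNAs were enriched more with AIN-2 than with GFP. The methyltransferase gene anmt-2 was higher (limma, adjusted p = 0.0297, n = 3 in each of 4 groups), with no size given because the AIN-2::GFP IP was the 1 group with samples above background. The ribosomal protein genes rps-3A and rpl-10L differed by -3.21 ± 0.50 and -3.43 ± 0.54 (adjusted p = 0.0466 each). These were the 3 features past the test. The difference was 4.07 ± 0.82 for sup-18 (adjusted p = 0.0747), 3.32 ± 0.74 for vit-2 (adjusted p = 0.124) and 2.49 ± 0.64 for hbl-1 (adjusted p = 0.171), none of which passed. The anmt-2 call rested on an AIN-2::GFP IP level that was at least 1.26-fold above total RNA (adjusted p = 0.00247) and a GFP IP difference short of the threshold (adjusted p = 0.15) with both groups below background.

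As a group, ribosomal protein genes stood apart in this difference, with a median of -2.65, 2 of 66 past the test and 61 adjusted over the list alone (camera, adjusted p = 9.1e-77; 0.0272 with an estimated correlation). All 6 vitellogenin genes were above 0, with a median of 1.88 and 3 past the test adjusted over the list alone (adjusted p = 2.85e-04; 0.0272 with an estimated correlation; 0.339 under cyclic loess). All 6 heterochronic genes were above 0, with a median of 0.87 and 2 past the test so adjusted (adjusted p = 0.00249, 0.0444 with an estimated correlation). All 10 described targets were above 0, with a median of 1.17 and 1 past the test so adjusted (adjusted p = 0.0015, 0.248 with an estimated correlation). Both lists hold hbl-1 and lin-29. The axon guidance list had a median of 0.78 (adjusted p = 0.0015; 0.314 with an estimated correlation) and the hypodermal list 0.68 (adjusted p = 0.0374; 0.248 with an estimated correlation; 0.095 under cyclic loess). Lower medians were found for the respiratory chain (-1.08, adjusted p = 6.53e-08; 0.251 with an estimated correlation), major sperm protein genes (-1.40, adjusted p = 0.00101; 0.37) and the proteasome (-0.64, adjusted p = 0.0015; 0.481). They were found too for collagens (-0.43, adjusted p = 0.00131; 0.481), translation factors (-0.32, adjusted p = 0.00887; 0.481), germline genes (-0.52, adjusted p = 0.00922; 0.481) and intestinal genes (-0.75, adjusted p = 0.0374; 0.481), the last value being the adjusted p with an estimated correlation. Mean scaling, which moved the all-feature median from 0.17 to -0.36, ended the translation factor (0.0939), proteasome (0.205), germline (0.28) and intestinal (0.309) calls, the last also lost without the low-signal filter (0.073).

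Same-numbered AIN-2::GFP and GFP samples deviated together, and with the replicate as a block 0 features passed the limma test of this difference (1809 at an unadjusted p under 0.05, against 980 without the block). All 13 list calls held with the block, and signalling genes and nuclear hormone receptors passed as well (adjusted p = 0.0279 and 0.0315, against 0.0693 each without it). The count of 3 became 146 without GFP IP replicate 1, and 1 without AIN-2::GFP IP replicate 3 or promoter GFP total RNA replicate 3. It was 0 (753 to 908 at an unadjusted p under 0.05 in limma) without 8 of the 12 samples. Mean scaling gave 0 (901 at an unadjusted p under 0.05) and cyclic loess 19. Calls of rps-3A and rpl-10L held only without GFP IP replicate 1, with adjusted p of up to 0.207 in the other fits. The anmt-2 call held in 4 of the 12 fits, with adjusted p of up to 0.179. The intestinal and hypodermal calls were each lost without 6 of the 12 samples (adjusted p of up to 0.238 and 0.123). The germline call was lost without AIN-2::GFP IP replicate 2 (0.0646) and GFP IP replicate 3 (0.129). The translation factor call was lost without GFP IP replicate 1 (0.0732).

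The 1 AIN-2 associated feature was anmt-2, and 0 were shared with the 316 AIN-1 associated features (0.0259 expected for independent sets). This number depends on the definition and setting: set directly against the GFP IP there were 185, with 50 units added 69 (54 shared) and with array quality weights 133 (99 shared). On simulated data the difference of enrichments called 1.52% of the features changed by 3. Without GFP IP replicate 1 there were 44 AIN-2 associated features, of which 25 were shared. It was 3 without GFP IP replicate 2, and 0 without 8 of the 12 samples.

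Because that overlap was empty, features above total RNA in both IPs were counted as well, a definition added after the data were seen. The genes with the largest mean of the AIN-1 and AIN-2::GFP values were pals-40 (at least 10.7-fold and at least 13.6-fold), npr-29 (5.48 ± 1.04 and at least 15.5-fold), sphr-1 (4.06 ± 0.76 and at least 14-fold), and sup-18 (4.10 ± 0.65 and 5.41 ± 0.58). Next came lron-15 (4.43 ± 0.78 and at least 5.95-fold), twk-28 (at least 20.4-fold and 3.72 ± 0.69), and smoc-1 (3.68 ± 0.69 and at least 17.6-fold). The others were pho-9 (3.95 ± 1.06 and 4.90 ± 0.95), bus-28 (at least 23.4-fold and at least 10.8-fold) and the AMPK subunit gene aakg-3 (at least 14.6-fold and at least 6.62-fold). Among them sup-18, twk-28 and bus-28 stayed past both tests in every leave-one-out fit. The AIN-1 IP calls were lost without N2 total RNA replicate 1 for lron-15 (adjusted p = 0.102) and sphr-1 (0.08), without N2 total RNA replicate 2 for npr-29 (0.0705), smoc-1 (0.0763) and aakg-3 (0.0956). They were lost without either for pals-40 (0.104 and 0.0563) and without each of the 5 samples for pho-9 (up to 0.184). The described target hbl-1 was past both tests too. Both IPs held 213 higher features (212 genes) and 223 lower. Independent lists would share 20.8 and 18.8 (Fisher's exact test, two-sided, p = 4.54e-179 and 1.4e-207). No feature was higher in the AIN-1 IP and lower in the AIN-2::GFP IP (20.3 expected), and 1 the other way round (19.3 expected). The comparisons share no sample but share each feature's spread, so the lists are not independent. Across features, which are not independent replicates, the log2 ratios over total RNA correlated at r = 0.632 (Spearman rho = 0.639), and the differences from the control IPs at r = 0.495 (rho = 0.468). The 213 became 68 under mean scaling, 56 and 52 without N2 total RNA replicates 1 and 2, and 90 to 152 without 1 of the other samples compared.

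**Figure D3:**
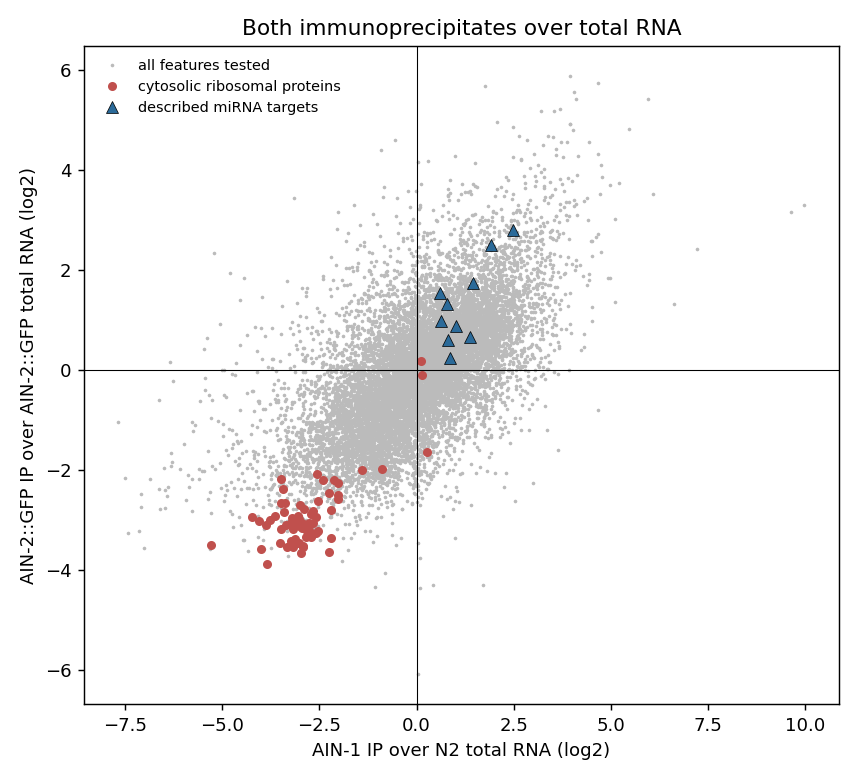
Log2 ratio of the AIN-1 IP over N2 total RNA (horizontal) against the AIN-2::GFP IP over its total RNA (vertical) for the 12222 tested features in grey, with ribosomal protein genes in red and described microRNA targets as blue triangles. Ribosomal protein genes have medians of -2.94 and -3.06, and all 10 described targets lie above 0 on each axis, with medians of 0.94 and 1.15.

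The total RNA of both transgenic strains was compared to see whether their expression differed before any immunoprecipitation. The gene unc-119, which is widely used as a transformation marker, fell by 3.67 on the log2 scale in the AIN-2::GFP strain relative to the other (SE 0.48, limma, adjusted p = 0.0132, n = 3 and 3). It was the 1 feature past the test, with 44 at an unadjusted p under 0.05. The described target hbl-1 differed by -0.05 ± 0.46. The unc-119 call was lost without each of the 6 samples (adjusted p of 0.0928 to 0.235). So 0 features passed in each of those fits (26 to 76 at an unadjusted p under 0.05). With the replicate as a block, where same-numbered samples deviated together, 0 passed in limma (2022 at an unadjusted p under 0.05). Major sperm protein genes had a median of -0.66 with 1 of 15 above 0 (camera, adjusted p = 1.17e-04; 0.702 with an estimated correlation), and ribosomal protein genes -0.21 (adjusted p = 0.0051; 0.961 with an estimated correlation). Other sperm genes had -0.25 (adjusted p = 0.0192; 0.396 with an estimated correlation) and muscle genes -0.22 (adjusted p = 0.0412; 0.961 with an estimated correlation). With the block the first pair held (0.00133 and 0.00652) and the other pair did not (0.179 each). Mean scaling also ended the other sperm and muscle calls (0.0579 each), and the muscle call was lost under cyclic loess (0.123), without the filter (0.121) and without the dye term (0.0619). The major sperm protein, ribosomal, other sperm and muscle calls were lost without 3, 3, 4 and 3 of the 6 samples (adjusted p of up to 0.15, 0.15, 0.68 and 0.91).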

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

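The 3 tests on array sets and the other scalings and leave-one-out fits of the AIN-1 minus AIN-2 difference were chosen only after the results were seen. This difference and the settings with transgenic total RNA, unlisted features and preimmune-detected features were added after the data were seen.

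Tests of a difference between enrichments singled out 4 features. The AIN-2::GFP enrichment differed from that of GFP by -3.43 for rpl-10L and -3.21 for rps-3A and was higher for anmt-2, whose fitted 3.88 is no measured size because 3 of the 4 groups had no sample above background. The AIN-1 enrichment was lower than that of AIN-2::GFP for F45D11.14 (limma, adjusted p = 0.0445; the fitted -6.63 is no measured size, as no AIN-1 or AIN-2::GFP IP sample was above background), the 1 feature past that test (696 at an unadjusted p under 0.05), which lay outside the naming rule and was named after its value was seen. F45D11.14 was at least 70.6-fold lower in the AIN-1 IP than in N2 total RNA (adjusted p = 5.41e-05), and did not pass between the AIN-2::GFP IP and its total RNA (adjusted p = 0.387). Against the transgenic total RNA samples F45D11.14 did not pass in the AIN-1 IP either (adjusted p = 0.759), so the call rests on the N2 total RNA. Its spot is among the 23 high in the N2 total RNA pair alone, which a shared array or the strain could give. With those samples on 1 array as a random block 0 features passed (limma, 601 at an unadjusted p under 0.05). Without N2 total RNA replicates 1 and 2 the number past this test was 38 and 8, and 0 (469 to 685 at an unadjusted p under 0.05 in limma) without AIN-1 IP replicate 2, AIN-2::GFP IP replicates 1 and 2 or AIN-2::GFP total RNA replicates 1 and 3.

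Gene lists that differed between the AIN-2::GFP and GFP enrichments under either correlation setting were ribosomal proteins (median -2.65), vitellogenins (1.88, mostly a GFP IP fall) and heterochronic genes (0.87). Between the AIN-1 and AIN-2::GFP enrichments vitellogenins had a median of -2.09 (0 of 6 above 0, 3 lower adjusted over the list alone, camera adjusted p = 3.49e-06; 0.00511 with an estimated correlation) and chemoreceptors 0.89 (358 of 472 above 0, adjusted p = 3.11e-05; 0.0266 with an estimated correlation). Both held without each of the 11 samples in turn. Over transgenic total RNA the AIN-1 IP chemoreceptor median was 0.54, against 0.37 for AIN-2::GFP over its own. N2 total RNA had -0.59, so much of the 0.89 came with the N2 reference. Past camera at the preset correlation alone were major sperm protein (1.71), other sperm (1.24), collagen (-0.72), muscle (-0.98) and neuropeptide genes (-0.47). N2 total RNA had the opposite sign for these and may be the source. Under mean scaling, relative to all genes, the vitellogenin median was -0.53 (adjusted p = 0.209) and the chemoreceptor median 0.63 (8.72e-05), with an all-gene median of -0.43. Strain and antibody differ together between these enrichments, so no cause can be assigned, but AIN-2::GFP IP replicate 1, of the array set of the AIN-1 IP, had medians of -0.69 and 0.15 for these lists, against -1.91 to -1.71 and 1.09 to 1.18 in the AIN-1 IP.

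Features not listed in the probe table were not part of the comparisons but carried signal. Of 3536 such features above the filter, 279 were higher and 96 lower in the AIN-1 than in the preimmune IP, and 1 was higher and 0 lower in the AIN-2::GFP minus GFP difference when tested with the gene features. All 3 AIN-1 IP samples had 2118 of the unlisted features above background, all 3 AIN-2::GFP IP samples had 2050, and all control IP samples had 416. There were 22 that were higher in every control IP sample than in every other sample, on the deposited scale, which divides by the sample mean and so raises constant signals in dim samples.

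Ribosomal protein mRNAs were lower than total RNA in both IPs, and 3 technical explanations were tested for AIN-2::GFP and 3 for AIN-1. The list median lay below that of all 1000 sets of genes matched on annotated gene length (difference of medians -2.73 for AIN-2::GFP and -2.85 for AIN-1) or on total RNA signal (-3.16 and -2.13), which argues against short genes and compression of bright spots. Each GFP IP sample lay at least 2.02 above every AIN-2::GFP IP sample, against a loss in any GFP immunoprecipitation, and AIN-2::GFP and GFP IP replicate 1, of the array set of the AIN-1 IP, lay at least 0.16 above the lowest other sample of their group. Directly against the preimmune IP the list had a median of -1.63, but all preimmune samples were dim, and how much of the AIN-1 fall came without the antibody stays open. A low share of ribosomal protein mRNAs bound by AIN proteins and RNA breakdown during the immunoprecipitation both stay open, as neither was tested.

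Of the calls between the AIN-1 and preimmune IPs, 80% were higher in the AIN-1 IP, where dim preimmune samples may be the cause. Of 1096 features above background in all preimmune samples 16% were called, against 11.4% of the 11126 others, and of those calls 43.4% (76 of 175) and 85% were higher. A share at least as high was written down beforehand as evidence against dim samples, but that bound was wrong, because it counted calls and not their direction. Features detected in the preimmune IP are also chosen by the level compared, and all 3 preimmune samples were dim. This test cannot tell dimness from enrichment by the antibody.

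The largest rises and falls of the AIN-1 IP over N2 total RNA rest on 2 total RNA samples, which may share 1 array, and on different array sets. Over the 10 largest rises the median ratio of the value against the 6 transgenic total RNA samples to that against N2 was 0.978, which argues against spots missing from the N2 arrays alone. For cdc-42 and asp-6 the array set stays open, as it was found in part from their spots. The other 8 rises were above background in AIN-2::GFP IP replicates 2 and 3, which argues against absent spots but leaves a partial shift open. Collagens had a median of -1.57 against the 6 transgenic total RNA samples (-1.83 against N2), which argues against the N2 profile as the source of their fall, but the muscle, intestinal, neuropeptide and other sperm calls were lost there and so rest on N2, and no biological explanation was tested.

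With 3 samples against 3 there are 10 splits, so the share of splits with as many calls cannot be under 0.05. The real split was the 1 with as many calls in each case: 1443 features between the AIN-1 and preimmune IPs, where the highest other split gave 14, whether or not it parted all 3 pairs. For the AIN-2::GFP IP over total RNA the real count was 673 and the highest other 0. For the GFP IP (3), the difference of enrichments (3), the total RNAs (1) and the AIN-2 associated features (1) the highest other was 0 as well.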

How the results depend on the processing

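Chosen only after the data were seen were the settings with array quality weights, with the array set as a covariate, against the 6 transgenic total RNA samples, with features without a gene, with preimmune-detected features alone, with N2 total RNA samples on 1 array and with GFP IP replicates 2 and 3 left out, and the leave-one-out fits of the lists. Signal over background limits the results: 1096 features were above background in all preimmune samples and 3207 in all GFP IP samples, against 7816 and 7191 in the AIN-1 and AIN-2::GFP IPs. Unless stated, the cause of a change was not tested. Median scaling was not run, because the median of preimmune IP replicate 1 is 0. Across settings, values of named genes kept their direction and their side of the threshold 13489 times, fell short of it in the same direction 1170 times, passed it newly 490 times and reversed 2 times. Named values short of the threshold changed direction 261 times. Values of the lists kept side and direction 1048 times, fell short 110 times, newly passed 40 times, and changed direction while short of it 76 times. Of the counts, 133 stayed within 1.5 times their value and 170 did not.

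Of the normalizations, mean scaling gave 2645 features for the preimmune IP over N2 total RNA (1597 as reported), 0 for the GFP IP (3 as reported; limma, 1236 at an unadjusted p under 0.05) and 0 for the difference of enrichments (3 as reported; 901). It gave 148 AIN-1 associated features (316 as reported), 0 AIN-2 associated (1 as reported) and 68 higher in both IPs (213 as reported), and called 9 lists in the AIN-1 IP over N2 total RNA and 8 in the GFP IP, against 16 and 4. Cyclic loess gave 0 for the GFP IP (limma, 1209 at an unadjusted p under 0.05), 19 for the difference and 0 AIN-2 associated. With 50 units added before log2 there were 1141 for the AIN-2::GFP IP over total RNA (673 as reported), 0 for the GFP IP (limma, 1282 at an unadjusted p under 0.05), 113 for the difference, 623 AIN-1 and 69 AIN-2 associated with 54 shared (0 as reported), and 421 higher in both IPs.

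Without the low-signal filter, which tests more features, there were 6 for the GFP IP, 44 for the difference, 2 between total RNAs (1 as reported), 18 AIN-2 associated with 12 shared, and 8 lists in the GFP IP. With the filter at the 50th percentile, which tests fewer, there were 0 for the GFP IP (limma, 894 at an unadjusted p under 0.05), 29 for the difference, and 10 AIN-2 associated with 7 shared. Without the dye term the GFP IP gave 5. A trended and robust variance gave 0 for the GFP IP (limma, 1316 at an unadjusted p under 0.05), 61 for the difference, and 19 AIN-2 associated with 15 shared.

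With only the groups compared in the fit, where fewer samples set the spread, there were 4218 for the AIN-1 IP over N2 total RNA (1437 as reported) and 3232 for the AIN-2::GFP IP. The same setting gave 28 for the difference, 8 AIN-2 associated, 852 higher in both IPs and 0 AIN-1 associated. It gave 0 in limma for the preimmune IP (1096 at an unadjusted p under 0.05), the AIN-1 against the preimmune IP (1476; 1443 past the test as reported), the GFP IP (926) and the total RNAs (475).

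With the replicate block, which also restricts each fit to the groups compared, 0 features passed in limma for the AIN-1 IP over N2 total RNA (5746 at an unadjusted p under 0.05), the preimmune IP over N2 total RNA (886), the AIN-1 against the preimmune IP (1000), the GFP IP (871), the difference (1809) and the total RNAs (2022). The block gave 2596 for the AIN-2::GFP IP over total RNA, and 0 AIN-1 associated, 0 AIN-2 associated and 0 higher in both IPs. An IP and its total RNA share only a number: same-numbered correlations were 0.0518 to 0.113 for AIN-2::GFP (other numbers -0.0854 to 0.00549) and 0.0229 to 0.0777 for GFP (other numbers -0.0759 to 0.0382). With N2 total RNA there are only 2 pairs, at -0.0204 to 0.0772 for the AIN-1 IP and 0.0336 to 0.0587 for the preimmune IP. Among the comparisons that the numbers pair, the block changed no list call other than those given in the report. In the AIN-1 IP over N2 total RNA it ended the germline (adjusted p = 0.109) and heterochronic (0.132) list calls. With same-numbered samples of opposite dye as a random block (consensus correlation 0.236) there were 2445 for the AIN-1 against the preimmune IP, 99 for the difference, and 53 AIN-2 associated with 37 shared. The N2 total RNA samples, which may share an array, were put on 1 as well (consensus correlation 0.279). There were then 953 for the preimmune IP over N2 total RNA, 2603 for the AIN-1 against the preimmune IP, 122 for the difference, and 64 AIN-2 associated with 36 shared. The asp-6 and vit-4 calls in the AIN-1 IP were lost (adjusted p = 0.0518 and 0.0584).

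Array quality weights gave 6045 for the AIN-1 IP over N2 total RNA, 4518 for the AIN-2::GFP IP, 1 for the GFP IP, 220 for the difference, 3 between total RNAs, 834 AIN-1 and 133 AIN-2 associated with 99 shared, and 1471 higher in both IPs. With the array set as a covariate there were 568 for the AIN-1 IP and 935 for the preimmune IP over N2 total RNA, 97 for the GFP IP, 5 for the difference, 70 AIN-1 and 3 AIN-2 associated, and 62 higher in both IPs. There cdc-42 in the preimmune IP reversed to -0.07. Against the 6 transgenic total RNA samples flp-7 reversed from -2.78 to 0.31 in the AIN-1 IP. With features without a gene tested too, there were 75 for the GFP IP, and 2 AIN-2 associated with 1 shared. Without GFP IP replicates 2 and 3 there were 7 for the GFP IP and 1 for the difference, with the lone GFP IP sample taken to vary like those of other groups. Features above background in all preimmune samples gave 479 for the AIN-1 against the preimmune IP (283 higher, 196 lower).

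Set directly against the GFP IP, the AIN-2::GFP IP differed at 518 features (363 higher, 155 lower), and 185 were then AIN-2 associated. The methods' t-test at the study's threshold gave 2326 AIN-1 and 1780 AIN-2 associated features with 1134 shared, and after Benjamini-Hochberg 1398 and 419 with 229 shared. Counting features past the test in the IP and not in the control IP gave 601 and 340 with 192 shared. With an estimated inter-gene correlation the lists past camera numbered 1 for the AIN-1 IP (16 as reported), 2 for the preimmune IP (11), 0 for the AIN-1 against the preimmune IP (6), 3 for the AIN-2::GFP IP (15), 1 for the GFP IP (4), 3 for the difference (13) and 0 for the total RNAs (4).

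Leaving out each sample in turn gave 278 to 882 features for the AIN-1 IP and 161 to 2618 for the preimmune IP over N2 total RNA, and 519 to 2497 for the AIN-1 against the preimmune IP. The range was 222 to 388 for the AIN-2::GFP IP, 0 to 573 for the GFP IP (limma, 905 to 1236 at an unadjusted p under 0.05 where 0 passed), 0 to 146 for the difference (753 to 908 where 0 passed) and 0 to 0 for the total RNAs (26 to 76). It was 65 to 327 for AIN-1 associated features, 0 to 44 for AIN-2 associated, 0 to 25 for those shared and 52 to 213 for those higher in both IPs. Without 1 of the N2 total RNA samples the lone other sample is taken to vary like the samples of other groups.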

Other observations

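The array sets, the comparison of N2 with transgenic total RNA, and the other scalings and leave-one-out fits of this part were chosen only after results were seen. The tests of gene families, of gene length and of the study's definition were chosen before.

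By the study's own definition 4481 of 17461 gene features met the first criterion in the AIN-1 IP and 2109 in the AIN-2::GFP IP, against 1092 in the preimmune IP and 621 in the GFP IP. AIN-1 associated were 2326, AIN-2 associated 1780 and both 1134 (237 if independent). After Benjamini-Hochberg the first criterion was met by 1485 and 429, against 2 and 0 in the controls, where weaker replicate agreement can lower counts. Then 229 associated features were shared (33.5 expected, Fisher's exact test, p = 1.2e-141). Unadjusted, 8 of 13 features of described microRNA targets were AIN-1 associated, 8 AIN-2 and 7 both. For ribosomal proteins the numbers were 1, 0 and 0 of 68. Of the miRISC factors, ain-1 was associated in both IPs, nhl-2 in the AIN-1 IP and alg-1 and alg-2 in the AIN-2::GFP IP.

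Total RNA of N2 differed from that of the transgenic strains at 127 features (80 higher, 47 lower, limma, 1579 at an unadjusted p under 0.05). That number was 20 without N2 total RNA replicate 2, 62 without replicate 1, and 47 to 79 without 1 of the other samples. Both N2 samples, of opposite dyes, appear to share 1 array: 23 features were high in this pair alone, against 28, 24 and 19 for same-numbered transgenic total RNA samples and 2 or fewer for any other pair. With such arrays as a random block 42 features passed (1128 at an unadjusted p under 0.05). Major sperm protein genes were lower in N2, with a median of -3.27 and 0 of 15 above 0 (3 lower, 13 adjusted over the list alone, camera adjusted p = 9.13e-14; 0.0434 with an estimated correlation). So were other sperm genes (median -1.24, 2 lower, adjusted p = 5.33e-09; 0.00788 with an estimated correlation) and chemoreceptors (median -0.59, adjusted p = 1.35e-04; 0.0434), while neuropeptide genes were higher (median 0.97, 60 of 76 above 0, adjusted p = 3.32e-08; 0.0434 with an estimated correlation). These 4 calls held under mean scaling and cyclic loess and without each of the 8 samples. So did those of collagens (0.51, adjusted p = 3.32e-08) and muscle (0.88, 6.11e-05), which were lost with an estimated correlation (0.207 each). A reason was not tested.

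Some spots gave signal in some samples and none in others in ways that follow neither strain nor RNA. Of 339 features that were clearly bright or dark in each non-control sample, 8 followed 1 split: cdc-42, T27E4.7, D1005.6, asp-6 and 2 unlisted features had signal in the AIN-1 IP, the preimmune IP and replicate 1 of the AIN-2::GFP and GFP IPs (D1005.6 was below the limit in preimmune replicate 1), and nlp-4 and aars-2 in the other 12 samples. Among the other possible splits of 14 samples into 4 and 10 (1001 in all), the highest number was 1. A shared array print is a candidate explanation of the split.

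Gene families outside the lists, with 10 or more measured members, were tested on the hypothesis that membrane and signalling families are enriched with AIN-2. Of 91 families 5 had a higher AIN-2::GFP than GFP enrichment: ptr (median 1.36, 21 of 22 above 0, camera adjusted p = 8.41e-04), abu (1.74), bus (2.20), dbd (1.83) and lron (0.90). The families mrpl (-0.64), mrps (-1.06), nspg (-0.87) and spig (-0.71) were lower. With an estimated correlation ptr, the patched-related receptors, was the 1 higher family left (adjusted p = 0.0358), and it held under mean scaling (8.53e-05), cyclic loess (0.00271) and without each of the 12 samples (up to 0.0252). The abu call was lost without GFP IP replicate 3 (up to 0.0529), the lron call without AIN-2::GFP IP replicate 2 or GFP IP replicate 1 (up to 0.262), and the mrps call without GFP IP replicate 1 (0.181). The dbd, mrpl, nspg and spig calls were each lost without 4 or more samples, and nspg also under mean scaling (0.0686) and cyclic loess (0.0552), while bus, short of the threshold with an estimated correlation (0.112), held in these fits. The ptr family also stood apart in the AIN-2::GFP IP over total RNA (median 1.36, 22 of 22 above 0, adjusted p = 4.01e-06; 0.00568 with an estimated correlation) and in the AIN-1 IP over N2 total RNA (1.42, 21 of 22 above 0, adjusted p = 0.00316; 0.0622 with an estimated correlation).

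Annotated gene length, a stand-in for transcript length that includes introns, was tested against the hypothesis that longer genes are enriched. Across 11760 genes, which are not independent replicates, it correlated with the AIN-2::GFP minus GFP enrichment at a Spearman rho of 0.184 (0.174 under mean scaling and 0.176 under cyclic loess). The value was 0.178 for the AIN-2::GFP IP and 0.126 for the AIN-1 IP over total RNA and 0.13 for the AIN-1 against the preimmune IP. In the control IPs over total RNA it was 0.0133 (GFP) and 0.0142 (preimmune), and between the total RNAs -0.0256.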
